A study of Homo sapiens with 6 samples.

How the data were processed

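Total RNA from 6 samples of Molt4 cells, 3 treated with 75 uM farnesol for 4 h and 3 with vehicle, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Spot intensities were extracted with Agilent Feature Extraction 9.5, per the submitters' processing notes, and 9.5.3.1, per the file headers. Per the file headers, the deposited processed signal is an intensity on a linear scale, subtracted for background and detrended, with small surrogate values where a spot did not exceed the noise. Such values compress the differences of dim probes. No normalization between arrays is named in the file headers. The deposited value table held the same intensity values, with a largest absolute difference of 0 from the processed signal of any spot. Its scale is therefore linear, it is not centred, and higher values are brighter. The column medians were 162, 166 and 181 for vehicle replicates 1 to 3 and 166, 142 and 138 for farnesol replicates 1 to 3.

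Each array held 45015 spots, of which 43376 were not controls, for 41000 probes. Control spots and spots marked as non-uniform or population outliers were left out, and saturated spots were kept. This left 221 probes without a value on at least 1 array, which were not tested. Log2 of the processed signal was reduced by the array's 75th percentile of it, and spots of a probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which 27812 probes were. A gene was represented by its kept probe with the highest mean signal, and 20750 genes were tested, 5283 of them with more than 1 kept probe. Among those, 8 had probes above 0.5 and below -0.5 at once.

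Probes were named through RefSeq accessions, or symbols, in a table of the GRCh38.p14 assembly, used for names alone. Of the probes, 23865 matched by accession, 2004 by current symbol and 965 by an older symbol, and 14166 kept the name in the files. Of the genes tested, 12842 had a matched symbol, and each remaining name in the files was counted as a gene. Probe coordinates are those of the files, on hg17 per the file headers.

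Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with a group term alone, and p-values were adjusted by the Benjamini-Hochberg method over all genes. An adjusted p of 0.05 and, where stated, a 2-fold change were the thresholds. Before the data were examined, 36 gene lists were fixed from textbook knowledge and from awareness that published work links farnesol to endoplasmic reticulum stress in leukaemia cells. Lists with at least 5 tested members, 33 of them, were tested with camera at a preset correlation of 0.01, adjusted over the lists. Member counts use the per-gene test over all genes and adjusted over the list alone. The latter makes no allowance for the number of lists, so single members can pass it by chance.

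Genes named in the text follow a rule set at the same time. It takes the 12 largest rises and falls among called genes, a set of fixed genes, up to 4 leading members that passed and the opposed member with the smallest p in each list described, and up to 5 genes per direction with the largest lower bound of the fold. As no gene passed over all genes, the first part named none there, and list examples are those that passed over the list alone. Genes that the fit with slide as a random block called, and the primary fit did not, were chosen after the data were seen. SLC7A11 was also singled out as the largest difference of its list after its value was seen. Some genes that the rule takes are not reported here. A gene not well above background on any array of a group has only a bound. The bound sets the bright group's mean against, per array, the higher of the dim probe's value and the lowest signal well above background.

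Slide was taken from the array identifier and tested as a block, as a random block (duplicateCorrelation, consensus correlation 0.54) and within each slide. With 2 slides the random block rests on little information about the variance between slides. It also takes the 1 correlation as known for all genes. Its p-values may thus be too small, and it called 74 genes where slide as a block called 3. No pair of arrays held identical values. The smallest standard deviation of a log2 difference between arrays was 0.28, for farnesol replicates 2 and 3. The alternatives tried were other background corrections and scalings, probe filters, flags, probe summaries, blocks, array weights, moderation, thresholds, list tests and leaving out each replicate. A correction for probe GC content (loess, span 0.5) was added after the data were seen.

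The fit was tested on simulated arrays with the means and spreads of the 20750 genes, with 100 genes changed at each of 2 sizes. With the spread of the fit without a slide term, 35% of genes planted at a log2 change of 1 and 93% of those planted at 2 were recovered. In a second simulation each gene's slide shift, estimated from these arrays, was added to the spread left after a slide term. The fit without a slide term then recovered 20% and 81%. Slide as a block recovered 84% and 96%, and slide as a random block 87% and 95%. False calls numbered 0, 11 and 7 in these 3 fits. As the slide shifts were built in, this simulation is no test of the genes called with a slide term. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.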

Results

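Messenger RNA was measured in Molt4 cells, an established human T-lymphoblastic leukaemia line, 4 h after addition of 75 uM farnesol or of its vehicle alone. Farnesol is a 15-carbon isoprenoid alcohol whose diphosphate is an intermediate of sterol synthesis. Each group held 3 samples, and each sample was hybridised to its own 1-colour oligonucleotide array. The labels do not say whether the 3 replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Between 66.8% and 71.4% of the non-control spots of an array were well above background, and the median processed signal lay between 157 and 208 fluorescence units. The number of arrays limits the precision. Levels are given as log2 signal relative to the 75th percentile of the array, and differences as farnesol minus vehicle.

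Arrays separated by slide before they separated by treatment. Slide 1 held vehicle replicates 1 and 2 with farnesol replicates 2 and 3, and slide 2 held vehicle replicate 3 with farnesol replicate 1. Across 19809 genes well above background on all arrays, the first principal component held 59.0% of the variance and the second 19.2%. The slide split accounted for 50.1% of the variance and the treatment split for 24.6%. Because each slide held both groups, the medians of the lists that passed and the differences of the list members said to have risen or fallen are also given within slides. Slide 2 held 1 array of each group, so its differences have no test.

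**Figure D1:**
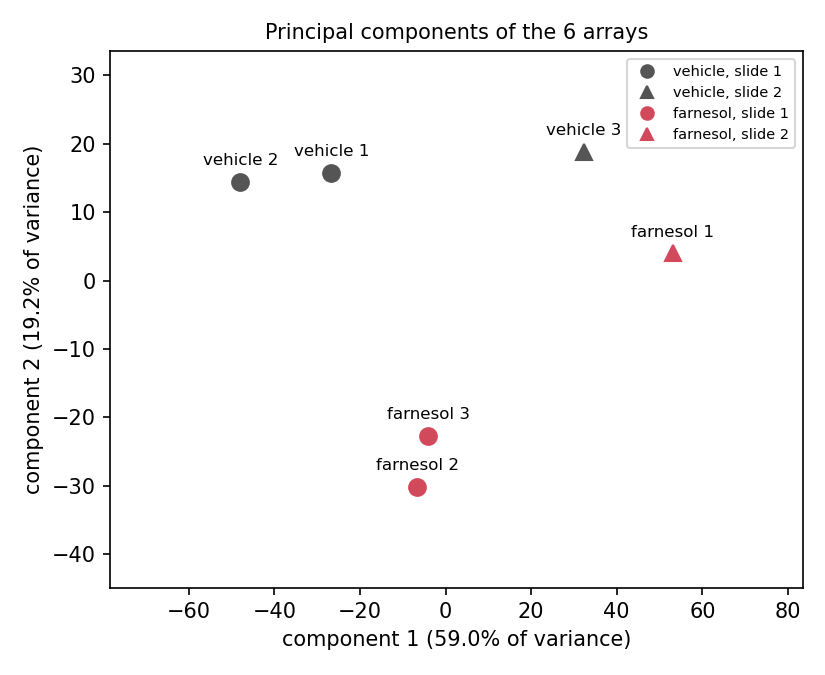
Scores of the 6 arrays on the first 2 principal components of log2 relative signal (horizontal axis, component 1 with 59.0% of the variance; vertical axis, component 2 with 19.2%), with colour for treatment and symbol for slide. Both slide 2 arrays lie at the right end of component 1, and within each slide the farnesol arrays lie to the right of the vehicle arrays. On component 2 every farnesol array lies below every vehicle array, with farnesol replicates 2 and 3 lowest.

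The comparison of farnesol with vehicle asks which genes differ in level after 4 h of exposure. CHAC1, a gamma-glutamylcyclotransferase that breaks down glutathione, had the smallest p of all genes, with a relative level of 0.68 ± 0.14 (SD, n = 3) in vehicle and 2.76 ± 0.22 (SD, n = 3) in farnesol cells. Its log2 difference was 2.08 with a standard error of 0.16, 2.01 within slide 1 and 2.20 within slide 2. The limma adjusted p was 0.0687 without a slide term, 0.0272 with slide as a block and 0.00601 with slide as a random block. In limma with the primary settings, which hold no slide term, no gene among the 20750 tested passed an adjusted p of 0.05 in either direction. At an unadjusted p under 0.05, 1227 genes were higher and 773 lower, where 1038 in all are expected by chance. With slide as a block, limma called 3 genes higher and 0 lower (2515 and 2384 at an unadjusted p under 0.05). These were CHAC1, the scavenger receptor gene CD163 and a transcript with no matched symbol. CD163 was not well above background in vehicle cells and was at least 1.17-fold higher (adjusted p = 0.0458 with that block). With slide as a random block limma called 67 genes higher and 7 lower, 51 and 1 of them at least 2-fold, the last a transcript with no matched symbol. That fit takes 1 correlation, estimated from 2 slides, as known for all genes, so its p-values may be too small. For 9 of the 74 called genes the chosen probe was well above background on no vehicle array. They were tested only because all 3 farnesol arrays passed the filter, so the balance of rises and falls rests partly on the filter. Within slide 1 alone, with 2 arrays of each group, 0 genes passed and 5392 had an unadjusted p under 0.05, and moderation with a trend and robust priors called CHAC1 alone (adjusted p = 0.036). Every farnesol array lay above every vehicle array for 2174 genes and below for 1304, together 16.8% of the genes. The mean share over the 10 splits of the arrays into 3 and 3 is 10%. Genes are not independent, so a single split can stray from that mean, and the excess is not a test.

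Genes that respond to amino acid shortage and to phosphorylation of the translation factor eIF2alpha, the targets of the transcription factors ATF4 and CHOP, were higher with farnesol as a list. Of 36 tested members, 35 had a positive log2 difference and 26 rose at an adjusted p under 0.05, adjusted over the list alone (29 with slide as a random block). None of them passed over all genes tested with the primary settings, and 13 did with slide as a random block. The median log2 difference of the list was 0.79, and it was 0.76 within slide 1 and 0.87 within slide 2. It stayed at 0.79 with ADM2, the member not well above background in vehicle cells, at its bound. The list was shifted upward in camera with a preset correlation (adjusted p = 1.14e-24), and in the same test with slide as a block (adjusted p = 2.13e-20). The call was lost with an estimated correlation (adjusted p = 0.405), and with fry, which tests whether its genes move one way on balance (adjusted p = 0.0588).

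By p, the leading members were CHAC1, CEBPB, SESN2 and JDP2. CEBPB, a leucine zipper transcription factor, rose by 1.82 ± 0.22 (SE). SESN2, an inhibitor of mTORC1, rose by 2.25 ± 0.32 (SE), and JDP2, a repressor of the AP-1 family, rose by 2.60 ± 0.39 (SE). These passed when adjusted over the list alone, with adjusted p values of 0.00185 for CEBPB and 0.002 for SESN2 and JDP2. SLC7A11, the cystine transporter subunit, had the largest log2 difference of the list, 2.73 ± 0.68 (SE), and its 3 probes gave values from 2.52 to 2.75. Transcription factor genes of the response rose as well when adjusted over the list alone: ATF3 by 1.70 ± 0.38 (SE), DDIT3, which encodes CHOP, by 0.88 ± 0.14 (SE), and ATF4 itself by 0.57 ± 0.13 (SE). The pseudokinase gene TRIB3 rose by 1.65 ± 0.42 (SE) and the asparagine synthetase gene ASNS by 1.00 ± 0.16 (SE). Over the other settings the ASNS difference ranged from 0.44 to 1.11. Within slide 1 the log2 differences of CEBPB, SESN2, JDP2 and SLC7A11 were 1.77, 2.05, 2.57 and 2.85, and within slide 2 they were 1.91, 2.65, 2.66 and 2.50. Those of ATF3, DDIT3, TRIB3 and ASNS were 1.61, 0.85, 1.66 and 0.97 within slide 1 and 1.88, 0.96, 1.61 and 1.05 within slide 2. ATF4 differed by 0.71 within slide 1 and 0.31 within slide 2. PPP1R15A, a phosphatase subunit that acts on eIF2alpha, had a log2 difference of 0.36 and did not pass (list-alone adjusted p = 0.0945, or 0.0198 with slide as a random block). The death receptor gene TNFRSF10B was the member with a negative difference, at -0.27, and did not pass either (list-alone adjusted p = 0.101).

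**Figure D2:**
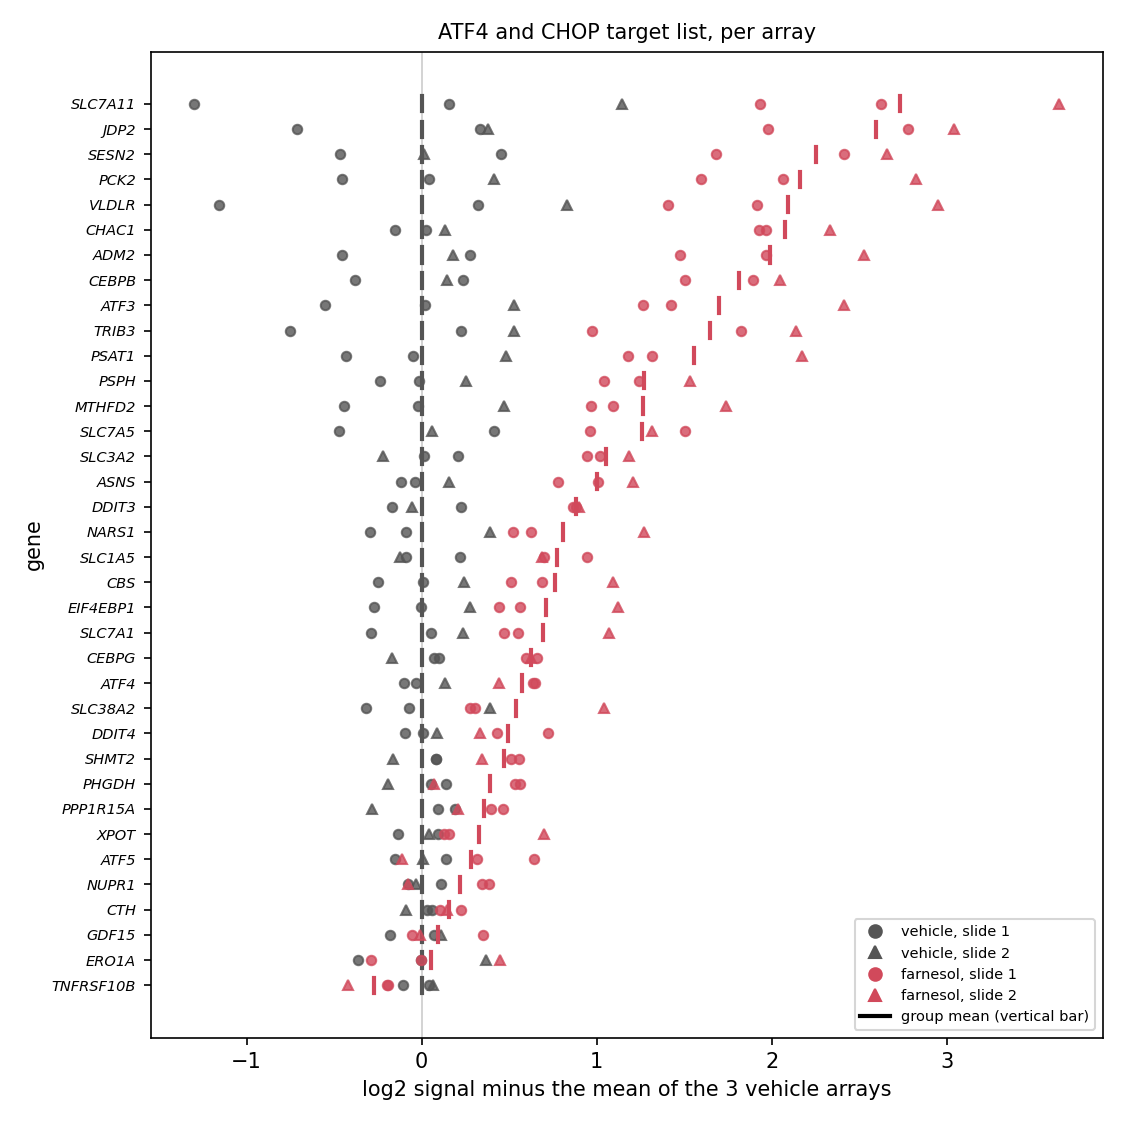
Log2 signal of the 36 tested members of the ATF4 and CHOP target list on each array, minus the mean of the 3 vehicle arrays (horizontal axis); each point is 1 array, vertical bars are group means, colour gives treatment and symbol gives slide. For 29 members every farnesol array lies above every vehicle array, and for TNFRSF10B every farnesol array lies below.

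On the genome build of the files (hg17), the CHAC1 probe lies on chromosome 15 from 39035814 to 39035873, the chosen ATF4 probe on chromosome 22 from 38243077 to 38243136, and the ATF3 probe on chromosome 1 from 209182251 to 209182310. The second ATF4 probe gave a log2 difference of 0.49. The DDIT3 probe spans chromosome 12 from 56197467 to 56197793 and the SLC7A11 probe chromosome 4 from 139446439 to 139446498. Exon and intron annotation of that build was not used here.

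Cytosolic aminoacyl-tRNA synthetase genes, whose products charge transfer RNAs, were also higher as a list in camera with the preset correlation (adjusted p = 0.0455). The call was lost with an estimated correlation (adjusted p = 0.791) and with fry (adjusted p = 0.117). Of 20 tested members 3 rose when adjusted over the list alone, and 17 did not pass. They were MARS1 (log2 difference 0.83), CARS1 (1.06) and TARS1 (0.64), the methionyl, cysteinyl and threonyl enzymes. Their differences were 0.93, 0.90 and 0.58 within slide 1 and 0.63, 1.37 and 0.77 within slide 2. With slide as a random block 7 members were higher and 2 lower when adjusted over the list alone, the latter QARS1 (-0.41, adjusted p = 0.0146) and KARS1 (-0.43, adjusted p = 0.0150), the glutaminyl and lysyl enzymes. Over all genes tested 0 members passed with the primary settings, and CARS1 did with slide as a random block (adjusted p = 0.0492). The list's median difference was 0.16, 0.17 within slide 1 and 0.31 within slide 2, and its camera adjusted p was 0.0382 with slide as a block and 0.191 within slide 1 alone. The call also ended with normexp (adjusted p = 0.479), quantile scaling (0.271), both together (0.400), median scaling (0.0556), array weights (0.429) and without genes shared between lists (0.106), in a range from 0.00164 to 0.479 over 26 camera fits. It ended without vehicle replicate 3, farnesol replicate 1 or farnesol replicate 3, where the adjusted p was 0.265, 0.128 and 0.0521.

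Chaperone and degradation genes of the endoplasmic reticulum, the targets of ATF6 and XBP1, did not pass as a list with the primary settings. The median log2 difference over 31 tested members was 0.02 (-0.04 within slide 1, -0.01 within slide 2, and -0.05 to 0.05 over the scalings), while the camera test leaned downward (adjusted p = 0.911; adjusted p = 0.979 with an estimated correlation). In 1 of 24 other camera fits, that with normexp, the list was lower (adjusted p = 0.0280, in a range from 0.0280 to 0.999). Its members went both ways. HSPA5, which encodes the chaperone BiP, had a relative level of 1.92 ± 0.47 (SD, n = 3) in vehicle and 0.58 ± 0.20 (SD, n = 3) in farnesol cells. It fell by 1.34 on the log2 scale when adjusted over the list alone (adjusted p = 0.0205), and did not pass over all genes (adjusted p = 0.357, or 0.107 with slide as a block). Its difference was -1.31 within slide 1 and -1.39 within slide 2, and its second probe gave -1.30. The chosen HSPA5 probe spans chromosome 9 from 125078978 to 125080023 on hg17, and the EDEM1 probe lies on chromosome 3 from 5235840 to 5235899. EDEM1, which delivers misfolded glycoproteins to degradation, rose by 0.97 when adjusted over the list alone (adjusted p = 0.0195) and over all genes with slide as a random block (adjusted p = 0.0412), with 1.00 within slide 1 and 0.91 within slide 2, while its second probe gave 0.37. HERPUD1 differed by 0.65, XBP1 by -0.28 and DNAJB9 by -0.02, and none of these passed without a slide term. Adjusted over the list alone with slide as a random block, 4 members were higher and 2 lower, among them HERPUD1 (adjusted p = 0.0433).

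**Figure D3:**
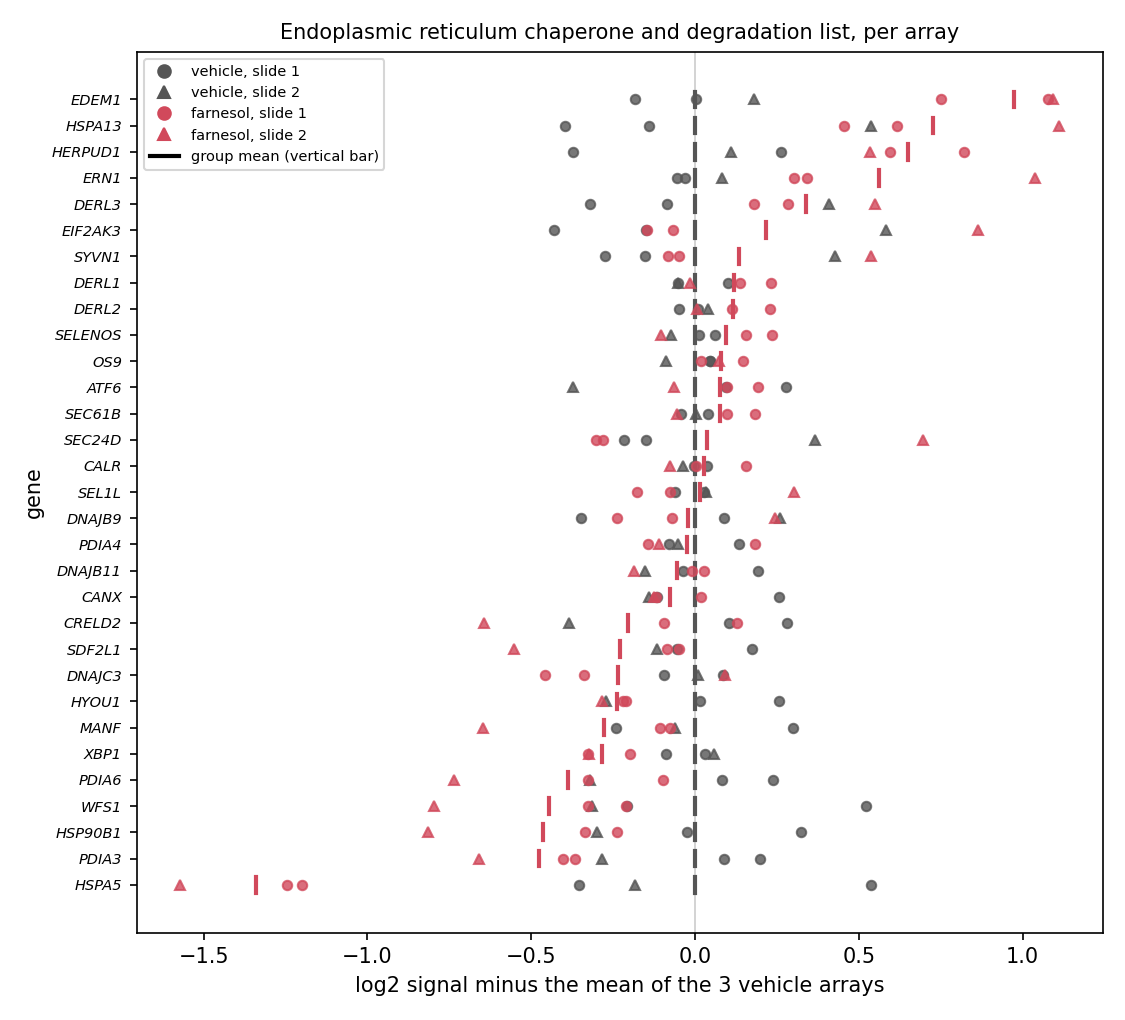
Log2 signal of the 31 tested members of the endoplasmic reticulum chaperone and degradation list on each array, minus the mean of the 3 vehicle arrays (horizontal axis), with points, bars, colours and symbols for arrays, group means, treatment and slide. HSPA5 lies lowest and EDEM1 highest, and most members scatter around 0.

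Lists of genes of the apoptotic machinery did not pass at 4 h. The list of pro-apoptotic BCL2 family and caspase genes had a median log2 difference of 0.05 over 19 tested members, and the list of BCL2-like survival genes and inhibitors of apoptosis 0.00 over 11. Death receptors and their ligands had a median of 0.09 over 11 tested members. Camera gave adjusted p values of 0.984, 0.920 and 0.984. No member of these lists passed when adjusted over its list alone. The BH3-only genes PMAIP1, BBC3 and BCL2L11 had log2 differences of 0.68, 0.05 and -0.24. The survival gene MCL1 differed by -0.03. The 2 BCL2 probes disagreed, at -0.78 and 0.34.

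Cholesterol synthesis and uptake genes, the targets of SREBP2, did not pass as a list with the primary settings, and their median had opposite signs on the slides. The median log2 difference over 24 tested members was -0.12 (camera adjusted p = 0.173; adjusted p = 0.979 with an estimated correlation). It was 0.14 within slide 1 and -0.81 within slide 2, which held 1 array of each group, and 0.06 without farnesol replicate 1. The list was lower in 7 of 24 other camera fits, in a range of adjusted p from 0.000145 to 0.999. These were normexp (adjusted p = 0.000145), quantile scaling (0.0320), both together (0.0186), every tested probe (0.0154), the mean of a gene's probes (0.0339), and the fits without vehicle replicate 2 (0.00915) or farnesol replicate 2 (0.0252). HMGCS1, a synthase of the mevalonate pathway, differed by -0.06 and INSIG1, a regulator of SREBP processing, by -0.44, and neither passed. Of 14 fatty acid synthesis genes, the fatty acid synthase gene FASN fell when adjusted over the list alone, by 0.72 on the log2 scale (adjusted p = 0.0498), and 13 did not pass. Over all genes the limma adjusted p of FASN was 0.384. FASN differed by -0.56 within slide 1 and -1.06 within slide 2. When slide was a random block, 1 member was higher and 2 lower, adjusted over the list alone. That list had a median of -0.25 and a camera adjusted p of 0.118 (adjusted p = 0.979 with an estimated correlation). Its median was -0.04 within slide 1 and -0.39 within slide 2, so most of the fall lay on the slide with 1 array of each group. It was lower in 4 of 24 other camera fits, with normexp (median -0.12, adjusted p = 0.0114), every tested probe (0.0423), the GC correction with the replicate block (0.0359) and without vehicle replicate 2 (0.00226), in a range from 0.00226 to 0.999. ABCA1, the sterol exporter and a target of LXR, differed by 0.77 (0.90 within slide 1, 0.51 within slide 2) and did not pass over all genes (adjusted p = 0.574) or over the list alone (0.199). With slide as a random block, and adjusted over the list alone, ABCA1 (adjusted p = 0.0332) and MYLIP (1.11, adjusted p = 0.0337) were higher and LPCAT3 (-0.41, adjusted p = 0.0332) lower among the 7 tested LXR targets. PCYT1A, the rate-limiting enzyme of phosphatidylcholine synthesis, differed by -0.20. The lists of prenylation, phosphatidylcholine synthesis, LXR target and fatty acid oxidation genes had medians of 0.09, -0.04, 0.05 and 0.08, with camera adjusted p values of 0.680, 0.364, 0.984 and 0.578.

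In lists of other stress responses single members passed, and no such list passed as a whole with the primary settings. Of 20 NRF2 target genes, NQO1, SLC7A11 and GCLC rose when adjusted over the list alone, by 0.69, 2.73 and 0.58, and 17 did not pass; SLC7A11 also belongs to the ATF4 list. NQO1 and GCLC differed by 0.53 and 0.72 within slide 1 and by 1.00 and 0.29 within slide 2. The haem oxygenase gene HMOX1 was not well above background on any array. Heat shock genes had a median difference of 0.03 over 22 tested members, and HSPA1A, whose sequence is nearly shared with a paralogue, differed by -0.32. Of 24 immediate early and MAP kinase feedback genes, 3 rose and 1 fell when adjusted over the list alone. DUSP6, a phosphatase of ERK, rose by 1.18 and the zinc finger gene EGR1 by 1.11, together with ATF3, and BTG2 fell by 0.58. DUSP6, EGR1 and BTG2 differed by 0.95, 0.86 and -0.47 within slide 1 and by 1.63, 1.62 and -0.81 within slide 2. DUSP6 also passed over all genes with slide as a random block (adjusted p = 0.0456). FOS differed by 0.99 and JUN by 0.40, and neither passed. Of 24 p53 targets, SESN2 alone passed over the list, BTG2 was also lower there with slide as a random block (adjusted p = 0.0153), and CDKN1A differed by -0.24. The NRF2, heat shock, immediate early and p53 lists had camera adjusted p values of 0.173, 0.911, 0.159 and 0.343. Of 24 other camera fits, 1 called each of 3 of these lists. The immediate early list was higher without the filter on dim probes (adjusted p = 0.00245, range 0.00245 to 0.644), the NRF2 list was higher with every tested probe (0.0423, range 0.0423 to 0.529), and the p53 list was lower with normexp (0.0390, range 0.0390 to 0.897). With an estimated correlation and the primary settings the adjusted p was 0.979 for each of these 3. Of 18 NF-kappaB targets, the activation marker CD69 rose when adjusted over the list alone, by 0.80 (adjusted p = 0.0435; 0.73 within slide 1, 0.94 within slide 2), in a list with a camera adjusted p of 0.911. The counts were 3 higher and 2 lower with slide as a random block, adjusted over the list alone.

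Mitotic genes were lower as a list in camera with the preset correlation (adjusted p = 0.0455). The call was lost with an estimated correlation (adjusted p = 0.979) and with fry (adjusted p = 0.690). All 29 G2/M and mitosis genes were tested and 23 had a negative difference, with a median of -0.14, which was -0.13 within each slide. None passed when adjusted over the list alone. The camera adjusted p was 0.0616 with slide as a block and 0.116 within slide 1 alone. An exact two-sided permutation test of the median over the 10 splits of the arrays gave p = 0.4. Median scaling (adjusted p = 0.0556), no filter on dim probes (0.232), array weights (0.512) and leaving out genes shared between lists (0.0574) also ended the call, in a range from 2.69e-07 to 0.512 over 26 camera fits. Leaving out vehicle replicate 2 or 3, or farnesol replicate 1 or 3, ended the call, with adjusted p values of 0.377, 0.111, 0.128 and 0.478. DNA replication and G1/S genes had a median of 0.07 over 33 tested members (adjusted p = 0.911). MYC differed by -0.13 and CCND3 by 0.07.

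T-lineage genes did not pass as a list (median -0.07 over 29 tested members, camera adjusted p = 0.911, a test that leaned upward). LMO2, a transcription cofactor gene activated in some T-cell leukaemias, rose by 1.52 ± 0.17 (SE) when adjusted over the list alone (adjusted p = 0.0019) and over all genes with slide as a random block (adjusted p = 0.0181), with differences of 1.39 within slide 1 and 1.78 within slide 2. The LMO2 probe lies on chromosome 11 from 33836819 to 33836878 on hg17. CD3E, a subunit of the T-cell receptor complex, differed by 0.01. Lists of erythroid and platelet, and of myeloid markers, checks for other cell types, held 5 tested members each, with medians of -0.30 and -0.20 and camera adjusted p values of 0.163 and 0.343. B cell and epithelial, stromal or endothelial marker lists held 4 tested members each, too few for the list test, with medians of -0.09 and -0.08, and none of the 8 bile acid receptor target genes was tested. Without the filter on dim probes these 8 had a median of -0.41 and a camera adjusted p of 0.00996, on probes that were not well above background on all arrays of either group, and the estimated correlation was not run there.

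**Figure D4:**
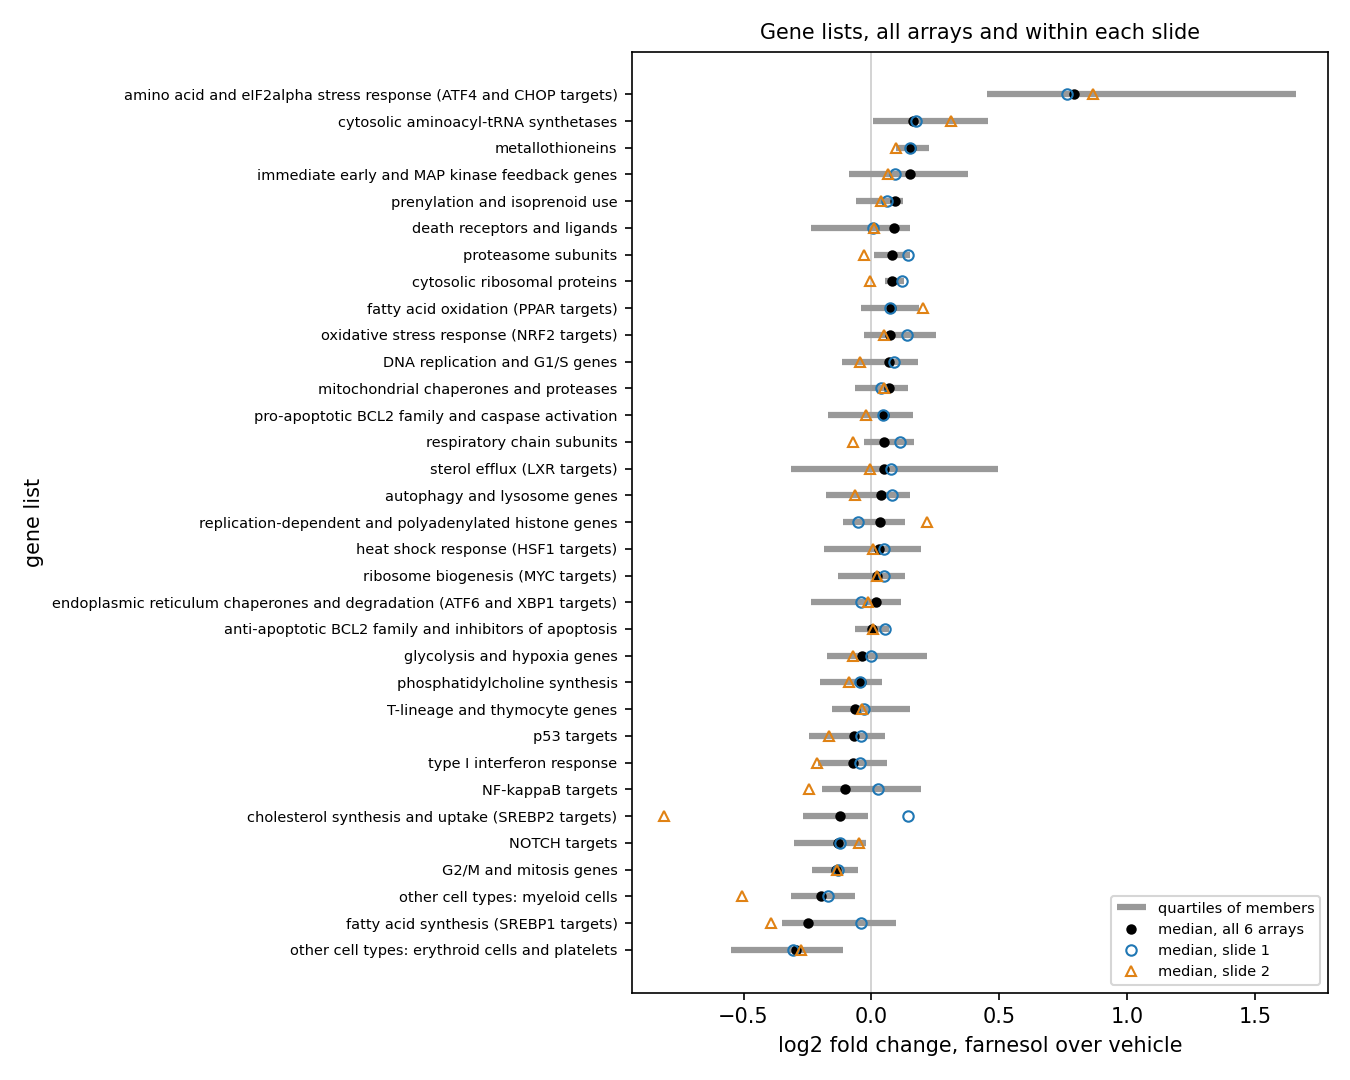
Median log2 fold change of farnesol over vehicle (horizontal axis) for each of the 33 tested gene lists; filled points are medians over all 6 arrays, open circles and triangles are medians within slide 1 and slide 2, and grey bars join the quartiles of the members. The ATF4 and CHOP target list lies highest, at 0.79, and the cholesterol list lies at 0.14 on slide 1 and at -0.81 on slide 2.

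The remaining lists did not pass in camera with the primary settings. Of the 30 lists that did not pass there, 20 passed in none of the 24 other camera fits. Ribosomal protein genes had a median of 0.08 over 37 tested members (adjusted p = 0.118) and metallothionein list genes 0.16 over 10 (adjusted p = 0.153). With an estimated correlation the adjusted p was 0.979 for both. The ribosomal protein list was higher in 11 of the 24 fits, in a range from 6.86e-05 to 0.984. These were the GC correction (median 0.17, adjusted p = 0.000161), alone or with slide (6.86e-05) or replicate block (0.00237), no filter on dim probes (0.00410), every tested probe (0.0121), the probe mean (0.0339), slide 1 alone (0.0199), array weights (0.0207), trend and robust moderation (0.0229), and the fits without vehicle replicate 2 (0.0230) or farnesol replicate 1 (0.000235). The metallothionein list was higher in 6, in a range from 0.00806 to 0.766. These were the GC correction (median 0.24, adjusted p = 0.0470), alone or with slide (0.0206) or replicate block (0.0413), no filter (0.0230), every tested probe (0.0303) and the fit without vehicle replicate 2 (0.00806). Proteasome and respiratory chain genes had medians of 0.08 and 0.05 (adjusted p = 0.343 for both, 0.979 with an estimated correlation). Without the filter both lists were higher (adjusted p = 0.0395 and 0.0357), as respiratory chain genes were without farnesol replicate 1 (0.0233), in ranges from 0.0395 and 0.0233 to 0.775. NOTCH targets and interferon response genes had medians of -0.13 and -0.07 (adjusted p = 0.364 for both). The adjusted p was 0.782 for histone genes, 0.911 for mitochondrial chaperones, 0.920 for glycolysis and hypoxia genes, 0.967 for ribosome biogenesis and 0.984 for autophagy and lysosome genes, with medians of 0.03, 0.07, -0.04, 0.02 and 0.04. Members of some lists passed, adjusted over the list alone, with slide as a random block and not without it. These were 2 higher fatty acid oxidation genes, 1 higher prenylation gene, 1 higher and 2 lower interferon response genes, 1 higher glycolysis and hypoxia gene, 2 higher autophagy and lysosome genes, and 1 lower erythroid marker. The camera test leaned against the sign of the median for the glycolysis and hypoxia, autophagy and lysosome, death receptor and BCL2-like survival lists. Over the scalings the median changed sign for the pro-apoptotic, phosphatidylcholine, heat shock, NF-kappaB, replication, ribosome biogenesis, ribosomal protein, respiratory chain, autophagy, mitochondrial chaperone, interferon, myeloid and erythroid lists.

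For 45 genes no probe was well above background on any vehicle array while the chosen probe was so on every farnesol array, which gives only a lower bound of the fold, above 1 for 42. Of the 45, 23 had a matched symbol and 9 passed over all genes with slide as a random block. For 3 genes the same held in the other direction. The lowest signal well above background was 13.3, 24.5 and 16.1 on vehicle replicates 1 to 3. On farnesol replicates 1 to 3 it was 12.3, 14.1 and 12.7. Passing on every array thus took a brighter signal in vehicle than in farnesol cells, so the 2 counts were not reached on equal terms. The glycine transporter gene SLC6A9 was at least 3.01-fold higher with farnesol (limma adjusted p = 0.384, or 0.0487 with slide as a random block). TSPYL6, ADM2 and ULBP1 were at least 2.29, 1.78 and 1.76-fold higher, with limma adjusted p values of 0.112, 0.243 and 0.383, or 0.0143, 0.0404 and 0.0487 with that block. These bounds hold for the processed signal with the percentile scaling alone. With normexp the log2 differences of SLC6A9, TSPYL6, ADM2 and ULBP1 were 1.07, 1.03, 0.89 and 0.76, and with normexp and quantile scaling 0.69, 0.58, 0.40 and 0.31. Among the 3, NAV2 was at least 1.88-fold lower (adjusted p = 0.562, or 0.224 with that block), while with normexp its log2 difference was 0.29. With the primary settings none of these 5 genes passed over all genes tested.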

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

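The GC corrections were chosen after the data were seen, and all other settings before. The counts of genes that passed over all genes, 0 in each direction, stayed 0 under every scaling, background, filter, flag, probe and threshold setting, within slide 1, with the replicate block and without any single replicate (0 to 0). Slide as a block gave 3 genes higher, 3 of them at least 2-fold, and slide as a random block 67 higher, 7 lower, 51 at least 2-fold higher and 1 lower. With the GC correction these were 3 and 3, and 48, 4, 41 and 1. Moderation with trend and robust gave 1 gene higher, CHAC1, at least 2-fold. Array weights gave 2799 higher, 1618 lower, 262 and 137 at least 2-fold, but their estimation stopped before convergence with a weight of 11.3 on vehicle replicate 1. The 3 shifted lists became 6 with normexp, 1 with the median scaling, 8 without the filter, 8 with every tested probe, 5 with the probe mean, 1 at an adjusted p of 0.01, 0 with an estimated correlation, 0 with fry, 1 without shared genes, 5 with the GC correction, 5 with it and the slide block, and 6 with it and the replicate block. Leaving out single replicates gave 1 to 6 lists, with 6 without vehicle replicate 2 and 1 without vehicle replicate 3 or farnesol replicate 3. Camera takes no random block, so the list test was not run with one. Normexp added the cholesterol, endoplasmic reticulum, fatty acid synthesis and p53 lists. No filter added the ribosomal, metallothionein, immediate early, proteasome, respiratory chain and bile acid receptor lists. The probe mean added cholesterol and ribosomal, and every probe also fatty acid synthesis, metallothionein and NRF2. The GC correction added ribosomal and metallothionein, and with the replicate block fatty acid synthesis. Leaving out vehicle replicate 2 added cholesterol, ribosomal, fatty acid synthesis and metallothionein, farnesol replicate 1 ribosomal and respiratory chain, and farnesol replicate 2 cholesterol. Both quantile scalings kept a count of 3 with cholesterol in place of tRNA synthetases. Slide 1 alone and array weights gave 2, ATF4 and ribosomal, and trend and robust 4, with ribosomal added. The cause of these differences was not tested.

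The ATF4 and CHOP target list passed in all 26 alternative camera fits with the preset correlation, with adjusted p values from 1.16e-31 to 5.27e-13, and did not with an estimated correlation (adjusted p = 0.405). The correlation estimated for this list was 0.20, where the preset was 0.01. The 26 include the main fit at an adjusted p threshold of 0.01. The tRNA synthetase and the mitosis list each passed in 15 of the 26, and neither with an estimated correlation (adjusted p = 0.791 and 0.979). Normexp moved the median of all genes to 0.13. The value table equals the processed signal, so no separate fit was run on it. The replicate block (same numbers across groups) called 0 genes and 3 lists. Same-numbered samples had correlated deviations of -0.34, 0.53 and -0.35 across genes. The negative values came from pairs on different slides, so these values cannot tell whether the numbers pair the samples. Within slide 1 the same-numbered pair had 0.53, and the other pairs of vehicle and farnesol arrays had 0.26, 0.24 and 0.28. Signal over background limits the dim genes: the chosen probe of 46 tested genes was not well above background on any vehicle array.

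The sign of the log2 difference changed for some genes that had not passed. STMN2 had passed with slide as a random block. Normexp gave BCL2L11 0.0095, NAV2 0.29 and STMN2 0.25. Quantile scaling gave BBC3 -0.034 and CCND3 -0.000713, and normexp with quantile gave BBC3 -0.041. Median scaling gave DNAJB9 0.0089 and MCL1 0.0037. Every tested probe gave BCL2 0.34 and CCND3 -0.099, and the probe mean gave CCND3 -0.015. Slide 1 alone gave CD3E -0.18, HMGCS1 0.50, JUN -0.17 and MCL1 0.052. Array weights gave CD3E -0.081, HMGCS1 0.34 and MCL1 0.015. The GC correction, alone or with any block, gave MCL1 0.013. Without single replicates, the differences ranged from -0.20 to 0.29 for BBC3, -0.072 to 0.25 for CCND3, -0.11 to 0.13 for CD3E, -0.20 to 0.11 for DNAJB9, -0.30 to 0.30 for HMGCS1, -0.21 to 0.75 for JUN, -0.087 to 0.053 for MCL1 and -0.35 to 0.033 for MYC.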

Other observations

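The tests of the slide structure and its GC content, of the within-slide differences, of the members separated between groups and of the gene counts, variance and list medians over other splits, and the genes called with slide as a random block, were chosen after the results were seen. Of the 74 genes that limma called with slide as a random block, 54 had a matched symbol and 13 belonged to the ATF4 and CHOP target list. Some of the transcripts with no matched symbol lie beside called genes. On hg17 such probes start at 48242219 on chromosome 20, near CEBPB (48242396), and at 187247082 on chromosome 3, near ETV5 (187247249). The 74 may thus hold more than 1 entry for a gene. Outside that list, the largest rises of genes with a matched symbol that were well above background on all arrays were those of ETV5, an ETS factor gene (log2 difference 2.05, adjusted p = 0.0195 with that block), MATN4 (1.81, adjusted p = 0.0195), PPP1R16B (1.59, adjusted p = 0.0493), RTP3 (1.55, adjusted p = 0.0195) and TMEM154 (1.55, adjusted p = 0.0412). Over the other settings these log2 differences ranged, in that order, from 1.02 to 2.63, 1.28 to 2.03, 1.17 to 2.03, 1.23 to 1.74 and 1.29 to 1.75. Falls included GDF10 (-0.94, adjusted p = 0.0404), MPHOSPH8 (-0.88, adjusted p = 0.0401), CXXC5 (-0.85, adjusted p = 0.0480) and STMN2 (-0.77, adjusted p = 0.0480), whose sign turned with normexp to 0.25. The 4 CXXC5 probes went from -0.49 to -0.92, while 1 of the 3 MPHOSPH8 probes gave 0.03. With the primary settings, which hold no slide term, none of these genes passed.

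The ATF4 and CHOP target list was higher with farnesol at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.405, or 0.999 with slide as a block) and with fry (adjusted p = 0.0588). The tables argue against probe GC content as the whole source of its median. Its value of 0.79 lay at percentile 100 of 10000 random lists matched on probe GC and signal, whose highest median was 0.18, and it was 0.87 after the GC correction. A slide shift cancels from the difference, as each slide held equal numbers of both groups, so the list's within-slide medians cannot test slide. The lower of the 2 was 0.76, and in 29 of 36 members every farnesol array lay above every vehicle array. A response to farnesol may underlie the shift, as a hypothesis, and an exact two-sided permutation test of the median over the 10 splits gave p = 0.1, the smallest this design can give, with 0.58 as the highest other size of the median; 6 of the 33 lists reached that p.

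The arrays separated by slide before treatment. Probe GC content followed the arrays, by a Spearman correlation across genes (which are not independent replicates). On slide 1 it was 0.36 and 0.44 for vehicle replicates 1 and 2 and 0.08 and 0.004 for farnesol replicates 2 and 3. On slide 2 it was -0.33 for vehicle replicate 3 and -0.43 for farnesol replicate 1. The correlation was thus lower with farnesol within each slide, so the GC trend was partly confounded with treatment as well. The first component still held 54.4% of the variance after the GC correction, so GC content was not the whole source of the separation by slide. The slide split ranked 1 of 15 splits into 2 and 4 arrays by variance explained. Slide may thus carry a technical difference, although replicates handled together would give the same split. The treatment split ranked 4 of 10 splits into 3 and 3, below 3 that were unbalanced over the slides, and 1 of the 6 balanced ones, with 24.6% of the variance against at most 14.4%, too few splits for a share under 0.05.

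HSPA5 was lower when adjusted over its list alone, while ATF4 targets were higher as a list at the preset correlation (adjusted p = 0.405 with an estimated correlation, 0.0588 with fry). Over all genes HSPA5 did not pass in limma without a slide term (adjusted p = 0.357), with slide as a block (0.107) or as a random block (0.0794), and of all settings run it passed with array weights alone (0.0106), whose estimation stopped before convergence. A faulty probe would leave the other probe at 0 or above, and it gave -1.30. Each slide held as many vehicle as farnesol arrays, so a slide shift cancels from the difference and the within-slide values cannot test it. The higher of these was -1.31. The HSPA5 difference ranged from -1.71 to -1.07 over the 28 other settings, among them the GC corrections, backgrounds and scalings. None of these choices removed the fall. A response to farnesol may underlie it, as a hypothesis, and no further technical explanation was tested.

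The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes, and 0 at least 2-fold, and so did all 10 splits, with a highest other count of 0. The real split shifted 3 lists, as 6 of the 10 splits did or exceeded, and the highest other count was 8, for vehicle replicates 1 and 3 with farnesol replicate 2 against the rest. The split of vehicle replicates 1 and 2 with farnesol replicate 2 against the rest, which lies close to the slides, had 3697 genes at an unadjusted p under 0.05 against 2000 for the real split. With slide as a block, 2 lists were shifted. For the tRNA synthetase list the exact two-sided permutation test of the median over the 10 splits gave p = 0.1, with 0.16 against a highest other size of 0.14. For the mitosis list the same exact test gave p = 0.4, with -0.14 against a highest other size of 0.23. Besides the ATF4 and tRNA synthetase lists, 4 lists that camera did not call with the primary settings reached p = 0.1 in this exact test, those of death receptors, fatty acid synthesis, NF-kappaB targets and DNA replication.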
